A study of Mus musculus with 4 samples.

How the data were processed

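Single-nucleus RNA was measured in 4 libraries (replicates 1 to 4) of the wild-type infarcted mouse heart at day 7, prepared with the 10x Genomics 3' kit, chemistry version 3.1, per the labels' protocols. The deposited files held raw UMI counts of 32285 genes for barcodes that had already passed the submitters' filter. Cell Ranger and the mm10 build were named per the submitters' processing notes, and a version of Cell Ranger is not given in the sources used here. Sequencing reads were not analysed here. Gene coordinates came from GENCODE mouse release M21 (GRCm38), which held 32158 of the gene identifiers (99.6%), 31436 of them under the same symbol, and all 142 named genes looked up.

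Nuclei with fewer than 300 genes or more than 5% mitochondrial UMIs were removed (24, 131, 288 and 162 in libraries 1 to 4, 605 in all), which left 1963, 7186, 9045 and 8826 nuclei. Doublets were scored per library by the share of simulated pairs among each nucleus's neighbours, and the highest-scoring nuclei were called up to a rate of 0.8% per 1000 nuclei, giving 31, 413, 654 and 623 (1721 in all), and clusters with at least 30% called doublets were set aside. Counts were scaled to 10000 per nucleus and log-transformed. The 2000 most variable genes outside the gene lists were centred within each library and reduced to 30 principal components. Nuclei were linked over 20 neighbours and clustered with the Leiden method at resolution 1 with 5 iterations and seed 1. A cluster was named where at least 3 markers of 1 of 18 marker lists were at least 2-fold higher than elsewhere and at 20 CPM or more, unless its 10 leading genes pointed to another class, or it was led by mitochondrial or respiratory chain transcripts. Names carry "-like" because the labels give no cell types, and 1714, 6048, 6627 and 7501 nuclei (21890) were named. Fibroblast-like nuclei were sub-clustered over all libraries and cardiomyocyte-like nuclei within each library (20 components, resolution 0.5), and sub-clusters with at least 3 raised markers were called activated or border-zone-like.

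UMI counts were summed per library and class, with at least 10 nuclei per sum and between 744953 and 15344400 UMIs in the sums compared. Each of 5 comparisons used edgeR's quasi-likelihood test with TMM scaling, its filter on low counts, a term for the library and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. Log2 fold changes are fitted and TMM-scaled, so they can differ from ratios of the plain CPM printed beside them. Per-library differences in gene levels were shared between the paired sums, with correlations across genes from 0.225 to 0.721, all above 0.1, so the library term was kept in all 5 comparisons. On simulated counts with 200 changed genes, 2-fold changes were recovered in 100%, 97%, 100%, 96% and 100% of cases and 4-fold changes in 100% of cases in each comparison. Of 13382, 12035, 12222, 11044 and 11008 unchanged genes, 9, 5, 13, 12 and 10 were called. The real fits called 10626, 7264, 6870, 2630 and 1744 genes, far more than the 200 simulated. These rates therefore do not measure error, including that of scaling, where so many genes differ. Classes were defined from the same counts that were then compared, so calls among genes used for clustering are partly built in. Counts outside those genes are given too, but such genes can vary together with the ones used, so these counts are not free of it.

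There were 16 gene lists with 468 genes, 467 of them in the files, none a cell type marker and all kept out of the genes used for clustering. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. The second form called no list in any comparison, also where the estimate lay below the preset value. A call lost there is therefore not evidence that correlation between genes made it. Members were also adjusted over the list alone. Genes were named by rule: a fixed set always (among them Gja1, Gja4, Gja5, Gjc1, Panx1, Scn7a, Kcnj2, Cacna1c, Slc8a1, Cdh2, Cdh11, Piezo1 and Trpm7), and from each list belonging to a comparison the 2 largest rises and the 2 largest falls among called genes with the same sign in every library and at least 20 CPM in 1 class. The text does not describe every gene chosen by this rule. All of them entered the screen of library values and the sensitivity counts, except some genes that are not reported here. Genes named outside the rule, including cluster leaders and the ratios of Gja1 to other transcripts, are described as such or were chosen after their values were seen.

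Free RNA was estimated from the unnamed cluster led by respiratory chain transcripts with the lowest median UMIs, taking the UMIs of the 12 cardiomyocyte markers in each class as its measure. Intervals of ratios of counts are exact at 95% and cover counting error only. Shares of nuclei with a UMI were also computed after thinning each nucleus to 1000 UMIs, with shallower nuclei left out.

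The comparisons, tests, marker and gene lists, the naming rule and the first set of alternatives were chosen before the data were examined. Chosen after were the fixed doublet rate with the score used here, after the automatic threshold of the Scrublet method had marked almost no nuclei, the joining of pericytes and smooth muscle as mural, the sub-clustering of cardiomyocytes within each library, the exclusion of sub-clusters led by the atrial gene Myl4 from border-zone-like nuclei, the treatment of clusters led by mitochondrial or respiratory chain transcripts as unnamed, and the free-RNA reference. The alternatives with free RNA subtracted and with libraries 3 and 4 only were also added after. The alternatives chosen before were DESeq2, RLE scaling, total counts, no filter on low counts, no library term, each library left out, a stricter filter (500 genes, 1000 UMIs, 2% mitochondrial UMIs), called doublets kept, listed genes kept for clustering, doubled resolution, thinned nuclei and all classes in 1 fit. The analysis used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.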

Results

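Nuclei from the infarcted hearts of wild-type mice, collected 7 days after myocardial infarction, were profiled by single-nucleus RNA sequencing, in which each nucleus carries its own barcode and each captured RNA molecule a unique molecular identifier (UMI). The 4 libraries, called libraries 1 to 4 here after their replicate numbers, belonged to 1 group. The labels state that nuclei of 3 hearts were mixed for the group and that 10000 nuclei were targeted. They do not say whether the libraries came from separate hearts, so p-values measure only the spread between these libraries, which may be technical. The title of the series asks how fibroblasts of the scar bear on the excitability of the heart and on arrhythmia. The comparisons were therefore made between classes of nuclei within the same libraries and centred on genes of cell junctions, ion channels, pumps and extracellular matrix.

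The deposited UMI counts held 1987 barcodes in library 1, 7317 in library 2, 9333 in library 3 and 8988 in library 4. Total counts were 17411174, 36337211, 37099485 and 36517637 UMIs, and the median per barcode was 5906, 2768, 2252 and 2252 UMIs in the same order. Library 1 thus had the fewest and the most deeply read nuclei. Pairs of libraries shared between 0.201% and 0.252% of the barcodes of the smaller one. Within each of the 4 large classes, gene counts of any pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of at least 2.50, so no library was a copy of another.

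After filtering, 27020 nuclei were clustered without the listed genes, and clusters were named from markers fixed beforehand. Fibroblast-like nuclei had the highest mean share, at 27.0% ± 2.21 (SD, n = 4 libraries) of all named nuclei, although cardiomyocyte-like nuclei exceeded them in library 3 (28.4% against 23.8%). Cardiomyocyte-like nuclei made up 22.6% ± 3.96, endothelial-like nuclei 18.5% ± 2.85 and macrophage-like nuclei 13.04% ± 2.43. Smaller classes were endocardial-like nuclei (5.42% ± 1.34), mural-like nuclei, which join pericytes and smooth muscle (4.42% ± 0.518), mesothelial or epicardial-like nuclei (2.55% ± 1.47) and lymphatic endothelial-like nuclei (2.08% ± 0.374). Proliferating-like nuclei made up 1.92% ± 0.7998, and dendritic, T or NK and B lymphocyte-like nuclei each less than 1%. Schwann-like nuclei numbered 31. The median depth of the large classes differed, at 7256 UMIs in cardiomyocyte-like, 2619 in fibroblast-like, 1524 in endothelial-like and 1257 in macrophage-like nuclei. Doublets and clusters that stayed unnamed took 12.7%, 15.8%, 26.7% and 15.01% of the barcodes left after filtering in libraries 1 to 4. A cluster of 882 nuclei led by mitochondrial transcripts held 852 nuclei of library 3.

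**Figure D1:**
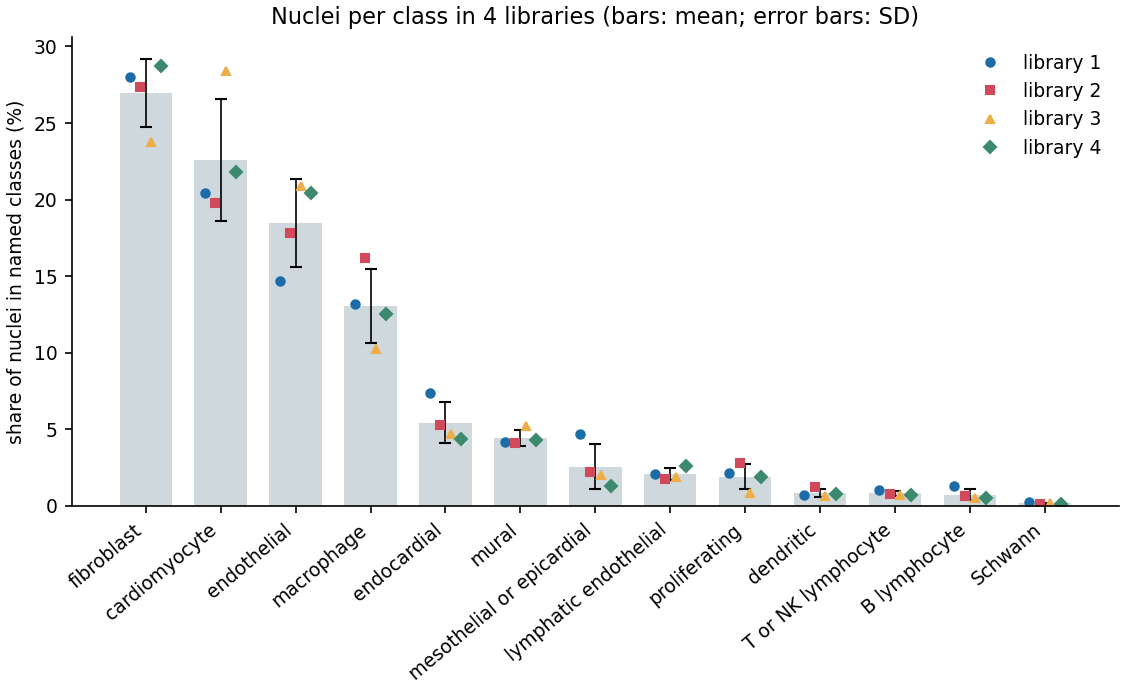
Share of nuclei in each named class, in percent of all named nuclei, with bars for the mean of 4 libraries, error bars for the SD and 1 symbol per library. Fibroblast-like nuclei had the highest mean at 27.0% ± 2.21, followed by cardiomyocyte-like nuclei at 22.6% ± 3.96.

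Fibroblast-like nuclei fell into sub-clusters of different activation. Sub-clusters with at least 3 raised activation markers, such as Postn, Cthrc1 and Fn1, were called activated and held 820 nuclei. Their share of fibroblast-like nuclei was 18.3%, 15.2%, 12.4% and 13.2% in libraries 1 to 4, with a mean of 14.8% ± 2.64 (SD, n = 4). Markers had to be raised over the other fibroblast-like nuclei, so a state shared by much of the class could stay uncalled. Before sub-clustering, a cluster whose leading genes included Col11a1, Cemip and Postn held 46.25%, 53.9%, 33.5% and 50.7% of fibroblast-like nuclei. Part of that cluster was therefore not called activated. The remaining fibroblast-like nuclei included a sub-cluster of 836 nuclei with a median of 1114.5 UMIs that was led by muscle transcripts such as Ttn, Mybpc3 and Myh6. Among cardiomyocyte-like nuclei, sub-clusters with raised border-zone markers such as Nppa, Ankrd1 and Myh7 held 875 nuclei. Border-zone-like nuclei made up 40.3% and 30.7% of the cardiomyocyte-like nuclei in libraries 1 and 2, and 10.2% and 10.7% in libraries 3 and 4. These shares depended on the clustering: in libraries 1 to 4 they were 6.27%, 15.9%, 9.55% and 10.9% with listed genes kept for clustering, 9.14%, 27.0%, 10.2% and 23.1% at doubled resolution, and 40.3%, 12.8%, 9.66% and 11.7% with called doublets kept.

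Most muscle nuclei of libraries 1 and 2 lay in another cluster than those of libraries 3 and 4. A cluster led by Xirp2, Xirp1, Abra and Ankrd1 held 88.0% and 78.3% of the cardiomyocyte-like nuclei of libraries 1 and 2. The same cluster held none of the 1882 such nuclei of library 3 and 1 of those of library 4. Its leading genes were found over all its nuclei, 936 from library 2 and 308 from library 1. These 4 genes were not higher in library 1 than in library 3. Over all cardiomyocyte-like nuclei, Xirp2 stood at 806, 4145, 2285 and 857 CPM in libraries 1 to 4, and Ankrd1 at 628, 1685, 758 and 528. In libraries 3 and 4, a cluster led by Myh7 held 52.2% and 29.99% of these nuclei, and a cluster led by Gm24474, Mylk4 and Kcnj3 held 27.0% and 56.5%. A further cluster held 4.29%, 12.6%, 20.7% and 13.4% in libraries 1 to 4. Cardiomyocytes were for this reason sub-clustered within each library.

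Sex-linked transcripts were mostly Y-linked in each library. Transcripts of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y gave 9107, 17967, 19263 and 19639 UMIs in libraries 1 to 4, while Xist, the transcript that silences the X chromosome in female cells, gave 10, 19, 21 and 12 UMIs. Nuclei with Y-linked and no Xist UMIs made up 86.3%, 68.0%, 65.4% and 66.1% of all barcodes, the median depth being 5906 UMIs in library 1 and 2252 to 2768 in the others. Nuclei with Xist and no Y-linked UMIs numbered 0, 3, 3 and 0.

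Connexins form the channels of gap junctions, which couple neighbouring cells electrically. Gja1, the main connexin of ventricular muscle (ENSMUSG00000050953, chromosome 10, 56377330 to 56402513, GRCm38), was highest in cardiomyocyte-like nuclei, at 147 ± 4.25 CPM (UMIs scaled to the class's summed total, SD, n = 4). It reached 93.8 ± 15.2 CPM in lymphatic endothelial-like, 89.2 ± 28.2 in mesothelial or epicardial-like and 70.5 ± 4.87 in endothelial-like nuclei. Fibroblast-like nuclei had 25.4 ± 1.79 CPM, and macrophage-like nuclei 30.8 ± 4.88. Gjc1, a connexin of conduction tissue and smooth muscle (ENSMUSG00000034520, chromosome 11, 102799579 to 102819700), had another order. It was highest in mural-like nuclei at 520.3 ± 79.8 CPM, followed by proliferating-like nuclei at 207 ± 48.2 and endothelial-like nuclei at 93.6 ± 10.6. Fibroblast-like nuclei had 38.9 ± 5.78 CPM of Gjc1 and cardiomyocyte-like nuclei 30.3 ± 2.64.

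Shares of nuclei with a Gja1 UMI were set beside those of macrophage-like nuclei. Unthinned, 6.77% of fibroblast-like nuclei and 4.67% of macrophage-like nuclei had a Gja1 UMI, at median depths of 2619 and 1257 UMIs. With every nucleus thinned to 1000 UMIs, which left 5435 fibroblast-like and 1851 macrophage-like nuclei, the shares were 2.41% and 2.43%, in classes whose free RNA was estimated at 14.5% and 29.6% of their UMIs. In cardiomyocyte-like nuclei, the share was 45.3% unthinned and 11.2% thinned. For Gjc1, thinned shares were 3.75% in fibroblast-like and 1.51% in macrophage-like nuclei.

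**Figure D2:**
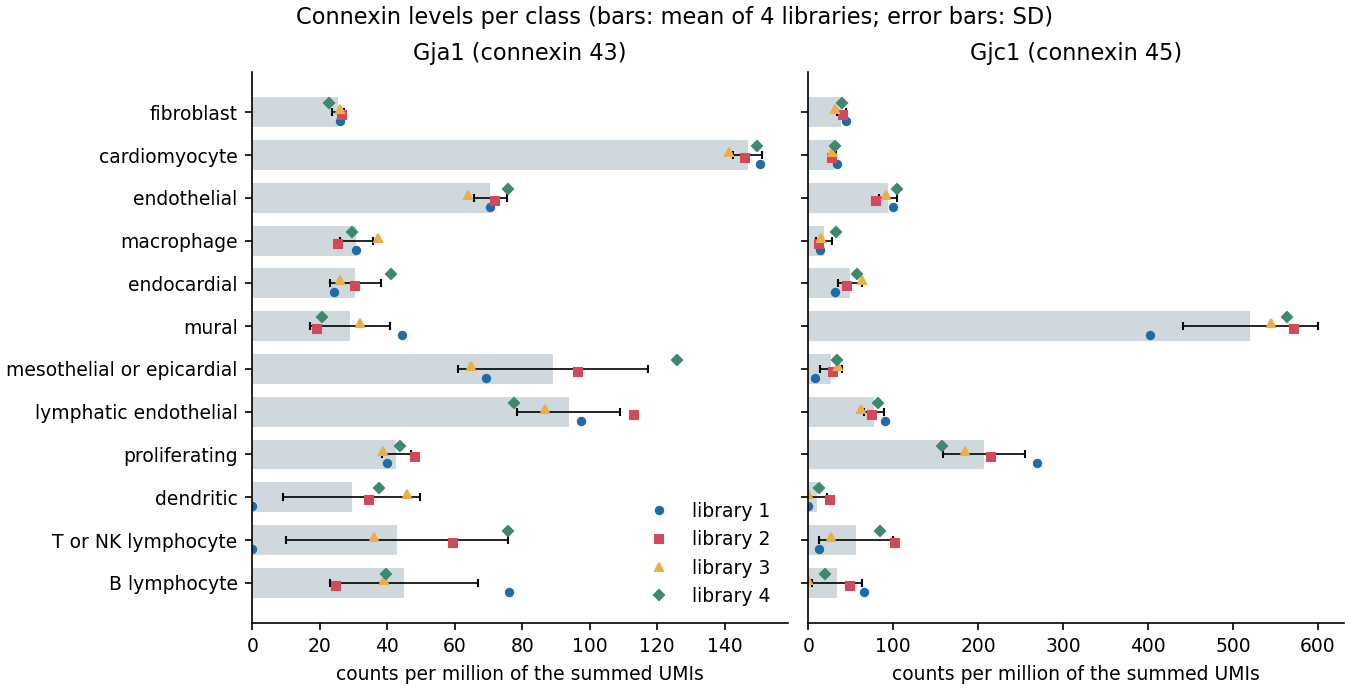
Levels of Gja1 and Gjc1 in CPM of each class's summed UMIs, with bars for the mean of 4 libraries, error bars for the SD and 1 symbol per library. Gja1 was highest in cardiomyocyte-like nuclei (147 ± 4.25 CPM) and Gjc1 in mural-like nuclei (520.3 ± 79.8 CPM).

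Because droplets also capture free RNA from broken muscle cells, Gja1 in fibroblast-like nuclei was set against muscle transcripts found in the same nuclei. Per 1000 UMIs of the cardiomyocyte markers, fibroblast-like nuclei held 10.1 ± 3.47 Gja1 UMIs (SD, n = 4), macrophage-like nuclei 5.76 ± 0.979 and cardiomyocyte-like nuclei 2.15 ± 0.199. The log2 ratio of fibroblast-like over cardiomyocyte-like nuclei was 2.17 ± 0.47, and that over macrophage-like nuclei 0.76 ± 0.26, both above 0 in 4 of 4 libraries. An exact sign-flip permutation test of 4 differences cannot reach 0.05, and both gave the smallest p it allows. A cluster of 1231 barcodes with a median of 644 UMIs, led by respiratory chain transcripts, served as the reference for free RNA and held 5.57 Gja1 UMIs per 1000. This is above the 2.15 of cardiomyocyte-like nuclei, so a class with free RNA alone would also exceed them. The ratio over cardiomyocyte-like nuclei therefore does not bear on free RNA. Scaled by the muscle markers, the reference predicted 297 Gja1 UMIs in fibroblast-like nuclei, where 499 were counted, a ratio of 1.68 (exact 95% interval 1.35 to 2.11, counting error only). All 4 libraries lay above the expected count. The expected counts came from the same reference, with 96 Gja1 UMIs, so the libraries are not separate tests. Gja1 stood at 26.0, 26.6, 26.2 and 22.7 CPM in libraries 1 to 4, but free RNA at 11.1%, 10.4%, 19.4% and 17.1%. The excess was thus larger in libraries 1 and 2, while the reference barcodes numbered 18, 353, 582 and 278. RNA of endothelial cells would bring 41.1% of the pooled excess, or 25.1% to 80.4% over the interval of the ratio. By library it would bring 12.9, 25.4, 15.3 and 29.2 Gja1 UMIs, a larger part of the excess in libraries 3 and 4. These endothelial values are overstated, since 205 of the 629 Gja1 UMIs of endothelial-like nuclei were themselves expected from free RNA. The ratio to free RNA was 1.02 (0.776 to 1.33) in macrophage-like, 3.07 (2.48 to 3.85) in endothelial-like and 0.860 (0.616 to 1.19) in mural-like nuclei. It was 2.08 (1.55 to 2.79) in activated and 1.60 (1.28 to 2.02) in other fibroblast-like nuclei, intervals that overlap. Gjc1, Panx1 and Scn7a stood at 5.52, 16.9 and 33.1 times the free-RNA level in fibroblast-like nuclei, whereas Kcnj2 at 1.01 and Pkp2 at 0.888 did not exceed it.

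**Figure D3:**
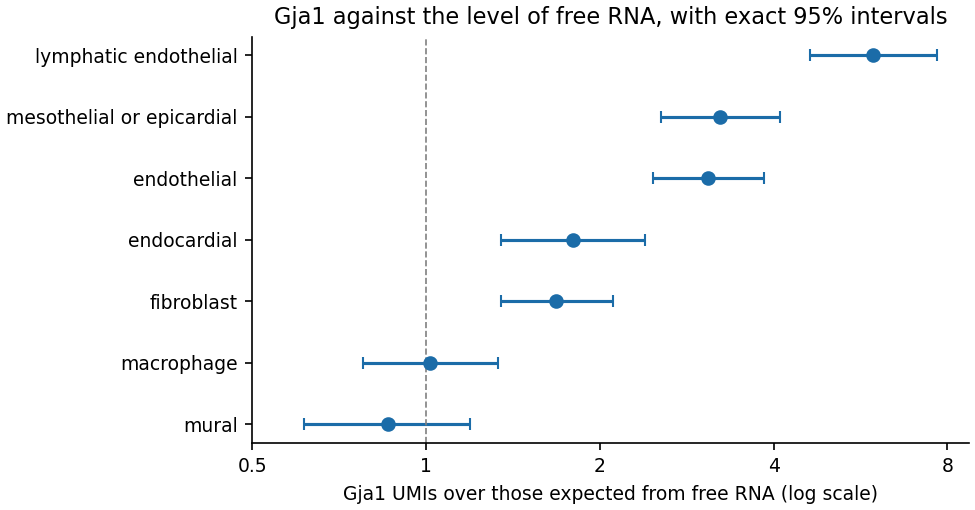
Gja1 UMIs in 7 classes divided by those expected from free RNA, on a log axis, with points for the ratio over 4 libraries and bars for exact 95% intervals of the counts. Macrophage-like nuclei lay at 1.02 and fibroblast-like nuclei at 1.68.

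The first comparison asked which junction and channel genes fibroblasts of the infarcted heart carried relative to muscle. Fibroblast-like nuclei had less Gja1 (log2 fold change -3.27 ± 0.10 SE, edgeR adjusted p = 3.94e-10, lower in 4 of 4 libraries) and far less of the desmosomal genes Pkp2 and Dsg2. They had far more of the pannexin channel Panx1 (ENSMUSG00000031934, chromosome 9, 15002128 to 15045478), of the atypical sodium channel Scn7a (ENSMUSG00000034810, chromosome 2, 66673425 to 66784914) and the sodium leak channel Nalcn, of the background potassium channel Kcnk2 and of the mechanosensitive channel Piezo2. Of 13830 genes tested, 5380 were higher and 5246 lower in fibroblast-like nuclei, 3554 and 3092 of them by more than 2-fold. Among 12396 tested genes that had not been used for clustering, 4270 were higher and 5041 lower.

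All 5 tested connexins and pannexins differed between fibroblast-like and cardiomyocyte-like nuclei, 2 higher and 3 lower, with the same counts adjusted over the list alone. Panx1 (38.8 ± 8.88 against 1.00 ± 0.539 CPM, log2 4.74 ± 0.26) and Gja4 (log2 1.99 ± 0.38) were higher, and Gja3 was lower (log2 -4.77 ± 0.19). Gjc1 was lower by log2 -0.38 ± 0.11 (adjusted p = 0.00737) although its plain CPM was higher, but the change turned to 0.36 with scaling by total counts and was not called with thinned nuclei (-0.07) or all classes in 1 fit (-0.35). Of 25 junction genes, 4 were higher and 19 lower. Pkp2 (log2 -4.94 ± 0.20), Dsg2 (log2 -5.43 ± 0.18) and the cadherin Cdh2 (log2 -3.4 ± 0.15) were lower, and the fibroblast cadherin Cdh11 (log2 2.82 ± 0.15) and Nectin1 (log2 4.6 ± 0.18) were higher. Camera called the junction list lower (adjusted p = 0.000487, limma). With an estimated correlation the adjusted p was 0.225, although the estimate, -0.0373, lay below the preset 0.01.

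Of the 6 sodium channel genes tested between fibroblast-like and cardiomyocyte-like nuclei, 4 were higher and 2 lower. Scn7a stood at 542 ± 80.3 against 7.53 ± 1.66 CPM (log2 5.48 ± 0.16) and Nalcn at 113 ± 27.7 against 2.52 ± 0.918 (log2 4.78 ± 0.13). Of 33 potassium channel genes, 12 were higher, led by Kcnk2 (log2 5.99 ± 0.16) and Kcnn3 (log2 5.23 ± 0.24), and 21 lower. The lower ones included Kcnd3, which carries transient outward current (log2 -5.42 ± 0.19), the background channel Kcnk3 (log2 -5.35 ± 0.19) and the inward rectifier Kcnj2 (log2 -3.88 ± 0.17). Calcium genes split into 11 higher and 11 lower of 26. The calcium release channel Ryr2 (log2 -5.27 ± 0.25), its partner Casq2 (log2 -5.09 ± 0.25) and the L-type channel Cacna1c (log2 -3.89 ± 0.16) were lower, and Orai2 (log2 4.14 ± 0.20) and Itpr3 (log2 3.93 ± 0.19) higher. Cation and mechanosensitive channels gave 11 higher and 7 lower of 19 (8 lower adjusted over the list alone), with Piezo2 (179.5 ± 47.4 against 5.50 ± 1.62 CPM, log2 4.29 ± 0.14), P2rx7 (log2 3.49 ± 0.17) and Piezo1 (log2 1.47 ± 0.10) higher. Chloride channels gave 9 higher and 5 lower of 17, and pumps and exchangers 8 higher and 11 lower of 22 (12 lower adjusted over the list alone). The calcium pump Atp2a2 (log2 -3.60 ± 0.15) and the sodium-calcium exchanger Slc8a1 (log2 -3.28 ± 0.17) were lower, and the exchanger Slc24a3 (log2 4.82 ± 0.12) and the calcium pump Atp2b4 (log2 3.89 ± 0.15) higher. None of these channel and pump lists passed camera (lowest adjusted p = 0.0830, potassium channels, limma). The channel kinase Trpm7 was lower (log2 -1.05 ± 0.10). Pkp2, Dsg2, Kcnk3, Kcnj2 and Casq2 in fibroblast-like nuclei stood at 0.748 to 1.08 times the free-RNA level, so their folds against cardiomyocyte-like nuclei do not measure fibroblast expression. The folds of Ryr2 and Kcnd3 were close to those of Kcnk3 and Casq2 and may be set by free RNA as well.

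Matrix genes were higher in fibroblast-like than in cardiomyocyte-like nuclei. They rose in 26 of 30 collagens, 20 of 23 crosslinking genes, 24 of 34 proteases and inhibitors, 25 of 33 TGF-beta genes and 25 of 33 Wnt genes, and were lower in 3, 2, 7, 3 and 6. Examples are Col8a2 (log2 5.26 ± 0.28), the crosslinking enzyme Loxl3 (log2 4.82 ± 0.15), the protease Adamts10 (log2 5.20 ± 0.16), the TGF-beta binding protein Ltbp2 (log2 4.92 ± 0.16) and the Wnt receptor Ror2 (log2 5.08 ± 0.12), while Tgm2 (log2 -3.44 ± 0.21) and Wnt5b (log2 -1.98 ± 0.13) were lower. Camera called these lists higher, with adjusted p of 1.71e-06, 0.000192, 0.000487, 0.000227 and 0.000624 (limma). With an estimated correlation the adjusted p values were 0.261, 0.265, 0.265, 0.225 and 0.225. All 31 fatty acid oxidation genes and 27 of 29 sarcomere genes were lower in fibroblast-like nuclei, 1 sarcomere gene being higher. Their camera calls (adjusted p = 1.74e-10 and 8.58e-09, limma) were lost at adjusted p = 0.290 and 0.340 with an estimated correlation. Stress genes gave 9 higher and 8 lower of 23. Muscle markers made up 0.272% of the UMIs in fibroblast-like and 6.88% in cardiomyocyte-like nuclei. With scaling by total counts, the median of all genes moved from 0.02 to 0.75, 8702 genes were higher and 2862 lower, or 75.3% of calls higher in place of 50.6%, and the medians of connexins (-0.38 to 0.36), calcium genes (-0.08 to 0.65) and pumps (-0.30 to 0.43) turned sign.

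The second comparison set fibroblasts against macrophages, another abundant interstitial cell of the healing heart. Fibroblast-like nuclei had more of the channels Scn7a (log2 3.73 ± 0.13), Nalcn (log2 2.97 ± 0.16), Kcnk2 (log2 4.21 ± 0.22) and Kcnma1 (log2 3.25 ± 0.13), and of Panx1 (log2 1.29 ± 0.22). They had less of Kcnk13 (6.16 ± 1.87 against 269 ± 60.9 CPM, log2 -5.42 ± 0.13) and of the calcium-permeable channels Trpv4 (log2 -4.06 ± 0.17) and Trpv2 (log2 -3.12 ± 0.21). Gja1 gave log2 -0.21 ± 0.16 and an edgeR adjusted p of 0.279, with 1 of 4 libraries higher, so no difference was detected. With thinned nuclei the Gja1 change was 0.12 (adjusted p = 0.724). Subtracting the expected free RNA, an alternative chosen after the data were seen, gave no usable fold, since 135 of the 137 Gja1 UMIs of macrophage-like nuclei were expected from free RNA. Of 12434 genes tested, 3573 were higher and 3691 lower in fibroblast-like nuclei, 2015 and 1827 by more than 2-fold. Of 10800 genes not used for clustering, 3103 were higher and 2704 lower.

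By list, fibroblast-like against macrophage-like nuclei gave 2 higher of 3 connexins and pannexins, Panx1 and Gjc1 (log2 1.11 ± 0.21, which fell to 0.19 and was not called with called doublets kept). Junction genes gave 9 higher and 9 lower of 24 (11 lower adjusted over the list alone), with Nectin3 (log2 2.22 ± 0.16) and Nectin1 (log2 1.92 ± 0.20) higher and Pkp4 (log2 -1.05 ± 0.11) lower. Cdh11 was higher (log2 1.27 ± 0.17), but turned to -0.04 with called doublets kept. Sodium channels gave 3 higher and 2 lower of 6, potassium channels 12 and 12 of 25, and calcium genes 11 and 5 of 23 (12 higher adjusted over the list alone). Cacna1g was higher (log2 2.45 ± 0.26) and Cacna1d lower (log2 -2.60 ± 0.11). Cation channels gave 7 higher and 6 lower of 16, with Piezo2 (log2 2.28 ± 0.17) and Trpc1 (log2 2.19 ± 0.18) higher and Piezo1 (log2 -0.70 ± 0.10) lower. Chloride channels gave 5 higher and 8 lower of 16 (6 higher adjusted over the list alone), among them the volume-regulated channel subunit Lrrc8d (log2 -2.87 ± 0.10). Pumps and exchangers gave 10 higher and 9 lower of 22 (10 lower adjusted over the list alone), with Fxyd6 (log2 2.79 ± 0.16) higher and Slc9a9 (log2 -3.99 ± 0.10) lower. No channel, pump or junction list passed camera in this comparison (limma), and medians and means differed in sign for junction genes (-0.03 and 0.17, test up) and cation channels (0.27 and -0.09, test up).

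Further genes of cardiac excitation were compared between fibroblast-like and macrophage-like nuclei. Slc8a1 was lower (log2 -0.87 ± 0.09). Kcnj2 was called lower too, but was at the free-RNA level in fibroblast-like nuclei, and macrophage-like nuclei held more free RNA, so no fold is given. Cacna1c was higher (log2 0.38 ± 0.12, edgeR adjusted p = 0.0112), a call lost in 4 of 16 alternatives: without library 1 (0.32) or 2 (0.23), without the library block (0.32, adjusted p = 0.233) and with all classes in 1 fit (0.36). Cdh2 was higher (log2 0.36 ± 0.14, edgeR adjusted p = 0.0388), a call lost in 7 of 16 alternatives, with the smallest change without library 2 (0.22) and the highest adjusted p, 0.204, without library 1. Trpm7 was not called (log2 0.14 ± 0.09, edgeR adjusted p = 0.204).

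Matrix lists were higher in fibroblast-like than in macrophage-like nuclei, in 25 of 27 collagens, 16 of 22 crosslinking genes, 18 of 30 proteases and inhibitors (19 adjusted over the list alone), 21 of 32 TGF-beta genes and 23 of 24 Wnt genes. Lower members numbered 0, 5, 5, 4 and 1 (6 proteases adjusted over the list alone). Col8a1 (log2 3.18 ± 0.12), Pcolce2 (log2 3.29 ± 0.17), Adamts12 (log2 3.22 ± 0.16), Tgfbr3 (log2 2.90 ± 0.13) and Nkd2 (log2 3.47 ± 0.22) were higher, and Tgfbi (log2 -3.83 ± 0.10) and Adam33 (log2 -3.47 ± 0.15) lower. Camera's adjusted p values were 5.32e-09, 0.00148, 0.00332, 0.00145 and 5.68e-07 (limma), and 0.202, 0.202, 0.306, 0.274 and 0.202 with an estimated correlation. Fatty acid oxidation genes were lower in 17 of 31 and higher in 2 (adjusted p = 0.00520, and 0.202 with an estimated correlation, limma). Sarcomere genes were lower in 19 of 27 and higher in 3 (adjusted p = 0.00180, and 0.24 with an estimated correlation, limma). Free RNA, estimated from muscle markers, made up 14.5% ± 4.47 of the UMIs of fibroblast-like and 29.6% ± 9.01 of those of macrophage-like nuclei (SD, n = 4). Stress genes gave 4 higher and 9 lower of 23.

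The third comparison set fibroblasts against endothelial cells. Endothelial-like nuclei had more of every tested connexin, with Gja1 (log2 -1.56 ± 0.11, edgeR adjusted p = 2.00e-08), Gjc1 (log2 -1.34 ± 0.11), Gja5 (log2 -4.73 ± 0.37) and Gja4 (log2 -0.87 ± 0.28) all lower in fibroblast-like nuclei, whereas Panx1 was higher (log2 1.76 ± 0.14). The Gja4 call was lost in 4 of 15 alternatives, without library 2 or 3, with free RNA subtracted and with DESeq2 (highest adjusted p = 0.107, DESeq2). Fibroblast-like nuclei had more of Scn7a (log2 3.81 ± 0.10), Scn2a (log2 3.78 ± 0.26), Kcnk2 (log2 4.03 ± 0.20) and Kcnma1 (log2 3.59 ± 0.11), and less of the endothelial cadherin Cdh13 (139.7 ± 30.8 against 2717 ± 472 CPM, log2 -4.36 ± 0.17). Of 12603 genes tested, 3450 were higher and 3420 lower, 1695 and 1407 by more than 2-fold. Of 11123 genes not used for clustering, 3002 were higher and 2606 lower.

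Junction genes were lower in 16 of 24 (17 adjusted over the list alone) and higher in 5 in fibroblast-like against endothelial-like nuclei, with Pkp4 (log2 -3.57 ± 0.09) lower and Nectin1 (log2 2.47 ± 0.16) and Ank2 (log2 2.43 ± 0.09) higher (camera adjusted p = 0.00577, limma, and 0.317 with an estimated correlation). Sodium channels gave 4 higher and 2 lower of 6, and potassium channels 10 and 13 of 26, with Kcnq1 (log2 -3.06 ± 0.14) lower. Medians and means differed in sign for potassium channels (-0.32 and 0.21, test down) and cation channels (0.36 and -0.10, test up). Calcium genes gave 12 higher and 9 lower of 23, with Cacna1g (log2 3.1 ± 0.26) and Cacna1d (log2 2.25 ± 0.14) higher. Cation channels gave 8 higher and 4 lower of 17 (5 lower adjusted over the list alone), with Trpc1 (log2 1.88 ± 0.13) higher and Trpv4 (log2 -3.69 ± 0.13), Trpm3 (log2 -3.14 ± 0.15) and Piezo1 (log2 -1.69 ± 0.08) lower. Chloride channels gave 4 higher and 8 lower of 16, with Lrrc8c lower (log2 -2.46 ± 0.11). Pumps gave 9 higher and 10 lower of 22, with Slc24a3 (log2 2.87 ± 0.13) and Slc8a1 (log2 0.75 ± 0.09) higher. Of other genes always named, Kcnj2, at the free-RNA level in fibroblast-like nuclei, was called lower, and Cacna1c (log2 0.67 ± 0.13) and Cdh11 (log2 1.21 ± 0.13) higher. Cdh2 was higher (log2 0.61 ± 0.16) but not called without library 2 (0.51, edgeR adjusted p = 0.0538), and Trpm7 was not called (log2 0.09 ± 0.07, adjusted p = 0.311).

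Among matrix lists in fibroblast-like against endothelial-like nuclei, 23 of 29 collagens were higher and 5 lower (camera adjusted p = 8.93e-06, limma, and 0.317 with an estimated correlation). Crosslinking genes gave 15 higher and 5 lower of 22 (adjusted p = 0.009, and 0.376 with an estimated correlation), and Wnt genes 15 higher and 5 lower of 28, 6 lower adjusted over the list alone (adjusted p = 0.00577, and 0.333 with an estimated correlation, limma). Proteases and inhibitors gave 18 higher and 8 lower of 32 and TGF-beta genes 16 higher and 7 lower of 33, without a camera call. Col8a2 (log2 3.65 ± 0.19), Loxl3 (log2 3.4 ± 0.10), Mmp16 (log2 3.53 ± 0.17), Ltbp2 (log2 3.64 ± 0.11) and Ror2 (log2 3.5 ± 0.09) were higher, and Col28a1 (log2 -4.04 ± 0.23), the basement membrane collagen Col18a1 (log2 -2.94 ± 0.21), the inhibitor Timp4 (log2 -4.73 ± 0.20) and the endothelial receptor Eng (log2 -2.69 ± 0.08) lower. Sarcomere genes were lower in 21 of 27 and higher in 4 (adjusted p = 0.00251, and 0.317 with an estimated correlation, limma), with free RNA at 14.5% ± 4.47 of fibroblast-like and 21.9% ± 5.48 of endothelial-like UMIs (SD, n = 4). Fatty acid oxidation genes gave 5 higher and 13 lower of 31, and stress genes 5 higher and 11 lower of 23.

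**Figure D4:**
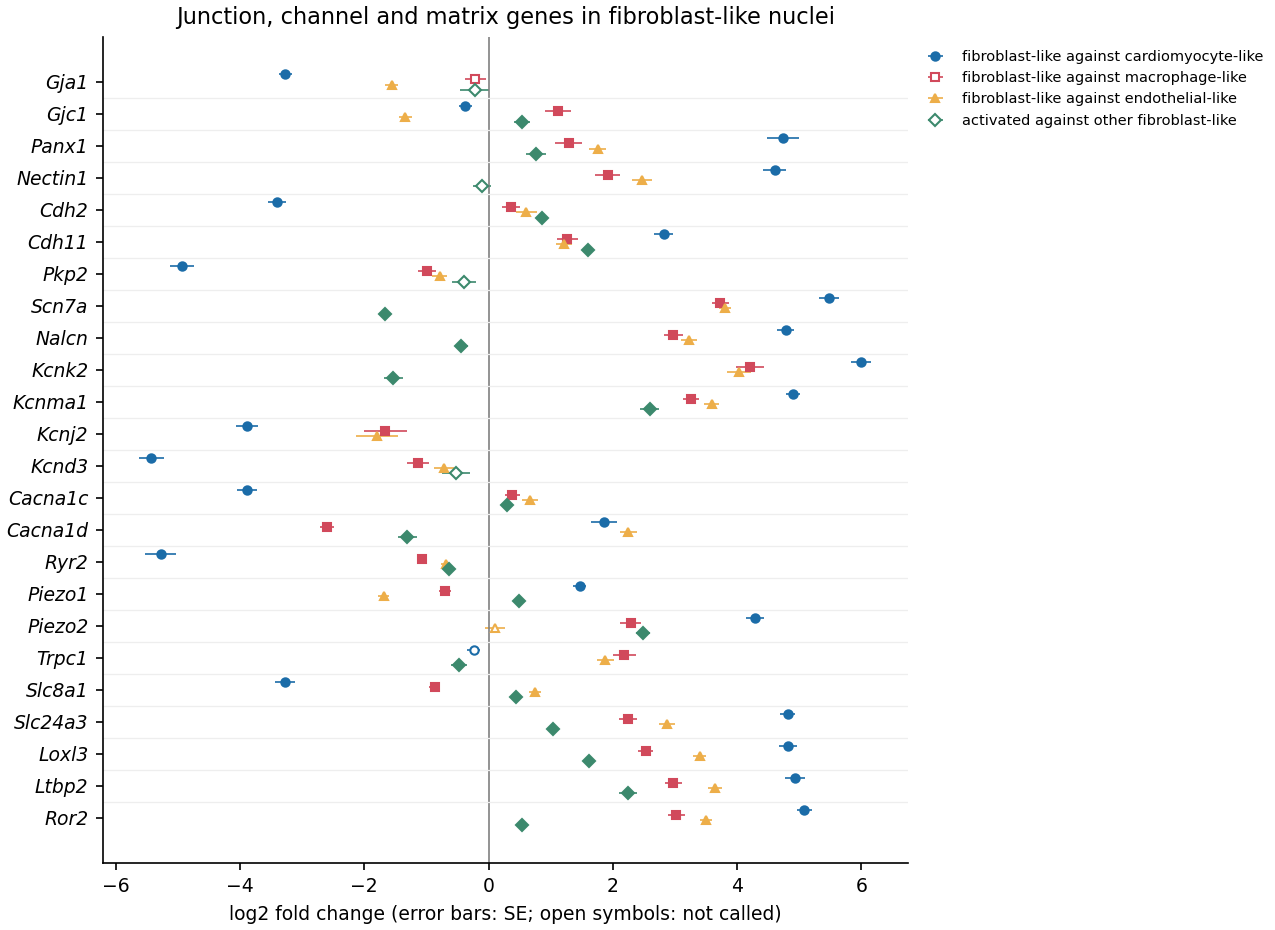
Log2 fold changes of 24 junction, channel and matrix genes in 4 comparisons of fibroblast-like nuclei, with bars for the SE and open symbols for changes that were not called. Scn7a was higher in fibroblast-like nuclei than in cardiomyocyte-like (5.48), macrophage-like (3.73) and endothelial-like nuclei (3.81) and lower in activated than in other fibroblast-like nuclei (-1.67).

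The fourth comparison asked how activated fibroblasts of the infarcted heart differed from the remaining fibroblasts. The latter included part of the cluster led by Col11a1 and Postn, so they cannot be read as a purely resting group. Activated fibroblast-like nuclei had more of the potassium channels Kcnq3, at 147 ± 35.4 against 8.35 ± 3.71 CPM (log2 4.14 ± 0.17, edgeR adjusted p = 3.15e-10, higher in 4 of 4 libraries), and Kcnma1, at 740.4 ± 165 against 125 ± 40.3 (log2 2.59 ± 0.15). Kcnk2 (log2 -1.53 ± 0.16) and Kcnt2 (log2 -1.32 ± 0.09) were lower. The activated nuclei joined a sub-cluster of 507 nuclei led by Thbs4 and Cilp and one of 313 led by Cemip, Col11a1 and Dkk2. The former held 44, 110, 164 and 189 nuclei in libraries 1 to 4 and the latter 44, 142, 31 and 96. Kcnq3 was among the leading genes of the former only. Its level was not compared between these sub-clusters, so its rise is that of the joined group. The sodium channel Scn7a fell to 199.8 ± 28.0 from 642 ± 77.0 CPM (log2 -1.67 ± 0.08), while Piezo2 rose to 482 ± 58.3 from 89.6 ± 28.9 (log2 2.48 ± 0.12). Of 11438 genes tested, 1356 were higher and 1274 lower, 425 and 410 by more than 2-fold. Of 9367 genes not used for clustering, 933 were higher and 692 lower.

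In activated against other fibroblast-like nuclei, 2 of 3 connexins and pannexins were higher, Panx1 (log2 0.76 ± 0.16) and Gjc1 (log2 0.54 ± 0.13, a call lost with DESeq2 at adjusted p = 0.0779, at doubled resolution and with all classes in 1 fit). Gja1 gave log2 -0.22 ± 0.24 and an edgeR adjusted p of 0.580, and the value was 0.04 without library 2 and -0.70, a called change, at doubled resolution. Junction genes gave 6 higher and 3 lower of 23 (8 higher adjusted over the list alone), with Cdh11 (log2 1.60 ± 0.09), Vcl (log2 1.06 ± 0.09) and Cdh2 (log2 0.86 ± 0.10) higher and Ank2 (log2 -0.66 ± 0.09) lower. Sodium channels were lower in 2 of 5 (3 adjusted over the list alone), with a camera adjusted p of 0.0304 (limma) and 0.300 with an estimated correlation. Potassium channels gave 6 higher and 6 lower of 23 (8 and 8 adjusted over the list alone), their median (-0.18) and mean (0.23) differing in sign and the test pointing down. Calcium genes gave 7 higher and 6 lower of 23 (9 and 8), with a median of -0.04, a mean of -0.09 and a test pointing up. Cacna1g (log2 1.10 ± 0.17) and Cacnb3 (log2 1.03 ± 0.17) were higher, and Cacna1d (log2 -1.30 ± 0.16) and Stim1 (log2 -0.92 ± 0.09) lower. Cation channels gave 5 higher and 3 lower of 15 (4 lower adjusted over the list alone), including Piezo1 (log2 0.49 ± 0.10, a call lost with thinned nuclei at 0.38, adjusted p = 0.153). Chloride channels gave 3 higher and 1 lower of 16, and pumps 5 higher and 7 lower of 21. Slc24a3 (log2 1.03 ± 0.10) and Slc8a1 (log2 0.44 ± 0.08) were higher, and Slc4a4 (log2 -0.94 ± 0.11) lower. Cacna1c was higher (log2 0.30 ± 0.08), a call lost without library 4 (0.31), without the library block (0.30) and with all classes in 1 fit (0.32, adjusted p = 0.375). Trpm7 was lower (log2 -0.22 ± 0.08, edgeR adjusted p = 0.0483), a call lost in 11 of 16 alternatives, among them any library left out.

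Matrix genes rose further in activated fibroblast-like nuclei, in 17 of 28 collagens (18 adjusted over the list alone), 13 of 22 crosslinking genes and 10 of 24 Wnt genes (12 adjusted over the list alone), with 5, 3 and 3 lower (5 Wnt genes adjusted over the list alone). These nuclei were chosen by raised markers such as Postn and Fn1, with which matrix genes can vary. The rise and the camera calls on it are therefore not free of that choice. Of the genes below, Col11a1, Dkk2 and Adamts16 led only the activated sub-cluster of 313 nuclei, not that of 507. Col22a1 (log2 4.53 ± 0.39), Col11a1 (log2 3.67 ± 0.17), P4ha3 (log2 2.08 ± 0.16), Dkk2 (log2 4.62 ± 0.24), Adamts16 (log2 3.36 ± 0.20), Ltbp2 (log2 2.25 ± 0.14) and Inhba (log2 1.70 ± 0.29) rose, while Col6a6 (log2 -3.19 ± 0.21), Col4a3 (log2 -2.38 ± 0.17), Adamts5 (log2 -1.69 ± 0.17) and Bmp4 (log2 -1.66 ± 0.16) fell. Camera's adjusted p values for these 3 lists were 0.000265, 0.00419 and 0.0135 (limma), and 0.337, 0.300 and 0.300 with an estimated correlation. Proteases and inhibitors gave 9 higher and 7 lower of 30, and TGF-beta genes 10 higher and 5 lower of 31 (11 higher adjusted over the list alone). Fatty acid oxidation genes were lower in 6 of 30 and higher in 1 (adjusted p = 0.00419, and 0.290 with an estimated correlation, limma). Sarcomere genes were lower in 15 of 27 (17 adjusted over the list alone) and higher in 4 (adjusted p = 0.00369, and 0.290 with an estimated correlation, limma). Free RNA made up 10.5% ± 3.22 of the UMIs of activated and 15.6% ± 4.58 of those of other fibroblast-like nuclei (SD, n = 4), the latter including the 836 nuclei led by muscle transcripts. Stress genes gave 1 higher and 1 lower of 23.

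The fifth comparison set muscle nuclei with raised border-zone markers against the other muscle nuclei. The place of the nuclei in the tissue was not measured. Border-zone-like cardiomyocyte nuclei had less of many potassium channels, with Kcnj3 (log2 -1.66 ± 0.14), Kcnv2 (log2 -1.43 ± 0.21) and Kcnj2 (11.2 ± 0.813 against 26.4 ± 2.83 CPM, log2 -1.20 ± 0.15, edgeR adjusted p = 0.000220) lower in 4 of 4 libraries. None of the 23 potassium channel genes was higher and 11 were lower (13 adjusted over the list alone). Genes of fatty acid oxidation, the main fuel pathway of the adult heart, were lower in 17 of 31 (21 adjusted over the list alone) and higher in none, with Slc27a1 at log2 -1.06 ± 0.11 and Acaa2 at -1.0 ± 0.11. Of 11360 genes tested, 865 were higher and 879 lower, 238 and 219 by more than 2-fold. Of 7422 genes not used for clustering, 394 were higher and 407 lower.

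Gja1 in border-zone-like against other cardiomyocyte-like nuclei gave 178 ± 37.8 against 142 ± 8.997 CPM (log2 0.33 ± 0.12) and missed the threshold at an edgeR adjusted p of 0.0890, with 3 of 4 libraries higher. It passed in 4 of 16 alternatives: without library 2 (log2 0.46, adjusted p = 0.0335), with listed genes kept for clustering (0.40), with thinned nuclei (0.53) and with libraries 3 and 4 only (0.62). Gjc1 was higher at 54.9 ± 29.6 against 24.5 ± 2.48 CPM (log2 1.09 ± 0.24, adjusted p = 0.00970), the pairs being 39.3 and 26.0, 29.9 and 26.7, 53.4 and 24.3, and 96.8 and 21.2 CPM in libraries 1 to 4, and RNA of mural cells was not excluded as part of its source. Gjc1 alone of the 3 connexins and pannexins was called, with 2 called when adjusted over the list alone. Junction genes gave 5 higher and 3 lower of 23 (4 lower adjusted over the list alone), with Afdn (log2 0.69 ± 0.11) and Ank3 (log2 0.63 ± 0.11) higher and Dsg2 (log2 -0.93 ± 0.09) lower. Sodium channels gave 2 higher of 5, a list whose median (-0.13) and mean (0.20) differed in sign, the test pointing up. Calcium genes gave 2 higher and 3 lower of 21 (7 lower adjusted over the list alone), among them Camk2d, a kinase that acts on calcium channels (log2 0.58 ± 0.09). Pumps and exchangers gave 3 higher and 2 lower of 20, with Slc24a2 higher (log2 1.16 ± 0.17) and the calcium pump Atp2a2 lower (log2 -0.69 ± 0.13). Cation channels were lower in 2 of 15 (1 higher adjusted over the list alone) and chloride channels lower in 2 of 16, including Ano4 (log2 -0.77 ± 0.11, a call lost with thinned nuclei at -0.53). Sarcomere genes gave 7 higher and 1 lower of 28 (8 higher adjusted over the list alone), with Synpo2l (log2 1.14 ± 0.10) and Des (log2 0.95 ± 0.10) higher and Synpo2 (log2 -0.88 ± 0.17) lower.

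In border-zone-like against other cardiomyocyte-like nuclei, Slc8a1 was higher (log2 0.37 ± 0.11, edgeR adjusted p = 0.0473), but this call near the threshold was lost in 10 of 16 alternatives, among them any library left out (0.27 to 0.43). Piezo1 (log2 0.35 ± 0.18, adjusted p = 0.224) was called in 4 of 15 alternatives: without library 1 (0.57, adjusted p = 0.0254), with listed genes kept for clustering (0.69), at doubled resolution (0.46) and with libraries 3 and 4 only (0.59). Cacna1c (0.24), Cdh2 (0.05), Cdh11 (-0.54), Scn7a (-0.44) and Trpm7 (-0.15) were not called (edgeR adjusted p = 0.16, 0.762, 0.104, 0.319 and 0.26), except Cacna1c with libraries 3 and 4 only (0.19).

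Camera called potassium channels (adjusted p = 0.000587), fatty acid oxidation (2.17e-08) and proteases (0.0308) lower and stress genes (0.00445) higher in border-zone-like nuclei (limma). With an estimated correlation the adjusted p values were 0.374, 0.374, 0.374 and 0.433. Stress genes gave 6 higher and 0 lower of 21 (9 higher adjusted over the list alone). Proteases and inhibitors gave 3 higher and 4 lower of 24 (8 lower adjusted over the list alone), collagens 4 higher and 3 lower of 23 (5 lower), crosslinking genes 4 higher and 1 lower of 18 (5 higher), TGF-beta genes 6 higher and 2 lower of 30 (7 higher) and Wnt genes 3 lower of 20. The other cardiomyocyte-like nuclei included sub-clusters led by fibroblast genes such as Dcn and Postn, with 345, 613 and 633 nuclei in libraries 2, 3 and 4 at medians of 2954, 2596 and 2942 UMIs, and 105 and 23 nuclei led by the atrial gene Myl4 in libraries 1 and 2. The median depth was 11646 UMIs in border-zone-like and 6396.5 in other cardiomyocyte-like nuclei. Without the library block, the fit called 178 genes higher and 86 lower and lost the calls of 21 genes named by rule. Without library 2, 571 were higher and 535 lower, without library 3, 512 and 475, and without library 4, 595 and 556.

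**Figure D5:**
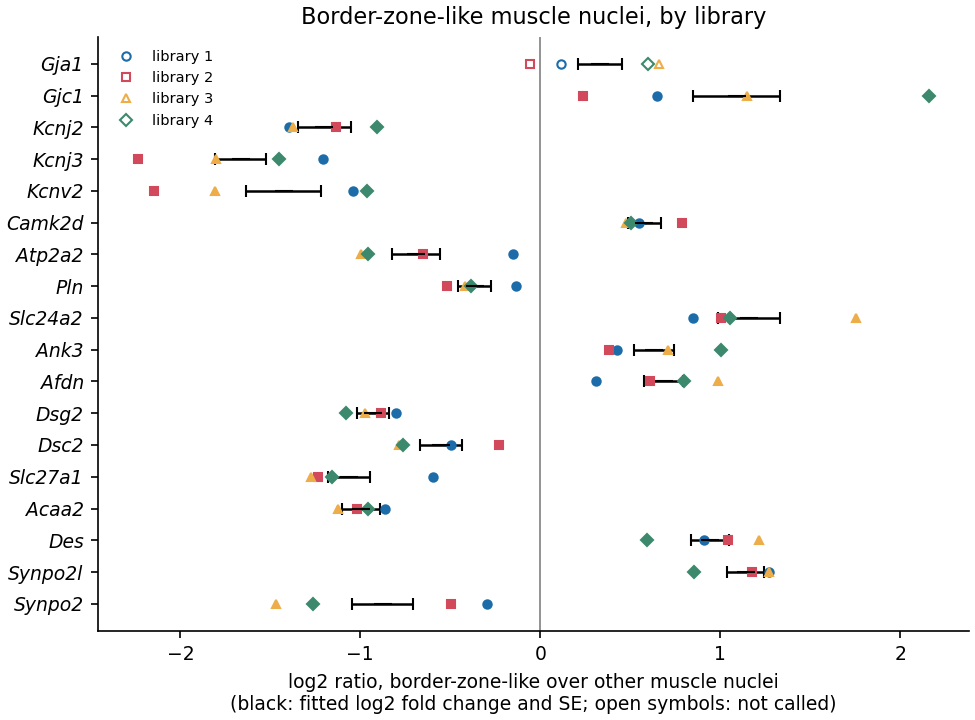
Log2 ratios of 18 genes in border-zone-like over other cardiomyocyte-like nuclei, with 1 symbol per library, black bars for the fitted change and its SE, and open symbols where the change was not called. Kcnj2 was lower (-1.20) in each library, while Gja1 was not called (0.33).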

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

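None of the 12 values below was picked by hand: 291 sets of 4 library values were screened for a library far from the other 3. Chance alone marks about 1 in 20 sets, or 15 of 291, and 12 were found, 5 of them in library 1, 2 in library 2, 2 in library 3 and 3 in library 4.

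Library 1 had 17411174 UMIs in total, against 36337211 to 37099485 in the others. Its median per barcode was 5906 UMIs, against 2252 to 2768. Gja1 in fibroblast-like nuclei was 22.7 CPM in library 4, against 26.0 to 26.6. Gjc1 in macrophage-like nuclei was 32.1 CPM in library 4, against 13.01 to 15.1. Gjc1 in mural-like nuclei was 402 CPM in library 1, against 545 to 572.

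Of log2 ratios of fibroblast-like against macrophage-like nuclei, Scn7a was 3.23 in library 4 (3.91 to 4.01 elsewhere), Ano4 1.32 in library 2 (0.35 to 0.44), Col8a2 4.19 in library 2 (2.60 to 2.70) and Adamts14 2.64 in library 3 (3.31 to 3.43). Of those against endothelial-like nuclei, Mmp16 was 5.29 in library 1 (3.20 to 3.38) and Fzd6 -3.09 in library 3 (-1.95 to -1.84). In border-zone-like against other cardiomyocyte-like nuclei, Ano4 was -0.36 in library 1 (-0.95 to -0.87).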

How the results depend on the processing

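The alternatives with free RNA subtracted and with libraries 3 and 4 only were chosen after the results were seen, and the others were planned. Over 245 named gene changes and 3949 values under alternatives, 3789 kept direction and side of the threshold, 141 lost a call, 10 gained one and 9 reversed. Genes that kept both under every alternative run numbered 52 of 55 in fibroblast-like against cardiomyocyte-like, 46 of 52 against macrophage-like, 54 of 56 against endothelial-like, 38 of 52 in activated against other fibroblast-like and 5 of 30 in border-zone-like against other cardiomyocyte-like nuclei. Calls were lost most often by Slc4a3 (11 of 16 alternatives) and Slc8a1 (10 of 16) in border-zone-like and by Trpm7 (11 of 16) and Trpm6 (10 of 15) in activated fibroblast-like nuclei. The cause was not tested for the values below unless one is given.

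Against cardiomyocyte-like nuclei, scaling by total counts gave 8702 higher and 2862 lower and turned Gjc1 to 0.36, Col4a2 to 0.24 and Acvr2a to 0.062, as the median of all genes moved to 0.75. Thinning to 1000 UMIs, which tests fewer genes, gave 3192 lower there, 2286 higher and 2271 lower against macrophage-like nuclei, 627 and 600.0 in activated fibroblast-like nuclei and 261 and 235 in border-zone-like nuclei. DESeq2 gave 834 higher and 813 lower in activated and 550.0 lower in border-zone-like nuclei. In the border-zone comparison, the fit without the library term gave 178 higher and 86 lower, and keeping listed genes for clustering 1453 and 1427. Leaving out 1 library gave there 512 (library 3) to 918 (library 1) higher and 475 to 846 lower, with fewer samples. The same ranges were 5110 to 5556 higher and 4821 to 5365 lower against cardiomyocyte-like, 3147 to 3522 and 3252 to 3486 against macrophage-like, 3084 to 3403 and 2799 to 3207 against endothelial-like, and 994 to 1222 and 934 to 1155 in activated fibroblast-like nuclei.

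Reversed gene values against macrophage-like nuclei were Cdh11 with doublets kept (-0.041), Gja1 thinned (0.12) and Gja1 with free RNA subtracted (2.18, no measured fold, since almost all macrophage-like Gja1 UMIs were expected from free RNA). In activated fibroblast-like nuclei, Gja1, not called, ranged with 1 library left out from -0.59 (without library 1) to 0.035 (without library 2), was 0.091 with free RNA subtracted and was called at doubled resolution (-0.70). In border-zone-like nuclei, Scn7a was 0.087 with libraries 3 and 4 only. Shares moved from 5.42% to 8.78% endocardial-like with doublets kept, and there to 24.4% fibroblast-like, 15.9% macrophage-like and 5.14% mural-like, and to 26.8% cardiomyocyte-like and 15.5% endothelial-like with the stricter filter, which removes shallow nuclei. The Gja1 to muscle-marker log2 ratio moved to 2.66 over cardiomyocyte-like nuclei with Ttn alone and to 0.43 over macrophage-like nuclei with doublets kept. The mean share of barcodes with Y-linked and no Xist UMIs moved from 71.5% to 49.2% when at least 2 UMIs were required.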

Other observations

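The tests of free muscle RNA and of cluster shares after thinning, and all counts of other splits, were chosen only after the results were seen, as were the genes named in the next 2 paragraphs.

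In border-zone-like cardiomyocyte nuclei, Tgfb2 (log2 2.33) was higher, as was the receptor Tgfbr1 (log2 0.91), while Tgfbr3 (log2 -0.69) and Tgfbr2 (log2 -0.50) were lower. The basement membrane collagens Col4a1 (log2 1.23), Col4a2 (log2 0.95), Col4a5 (log2 0.71) and Col4a6 (log2 0.96) were higher, and the fibrillar and other collagens Col5a2 (log2 -0.71), Col6a3 (log2 -0.82) and Col8a1 (log2 -0.59) lower, in a comparison whose other side included sub-clusters led by fibroblast genes. The called stress genes were Hspb1 (log2 1.49), Ier3 (log2 1.05), Atf3 (log2 0.70), Klf6 (log2 0.64), Jun (log2 0.55) and Hsp90aa1 (log2 0.48).

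Fibroblast-like nuclei held further sub-clusters. A set of 78 nuclei (5, 25, 17 and 31 in libraries 1 to 4) was led by Iigp1 and Ifit1 and had 7 raised interferon markers. Another of 749 nuclei was led by genes that included Pi16, Dpp4 and Sema3c. Activated nuclei comprised 507 led by Thbs4 and Cilp and 313 led by Cemip, Col11a1 and Dkk2, the latter with 44, 142, 31 and 96 nuclei in libraries 1 to 4. Macrophage-like nuclei formed a cluster led by F13a1, Cd163 and Mrc1 (38.5%, 46.9%, 70.1% and 67.1% of the class in libraries 1 to 4) and one led by Gpnmb, Ms4a7 and Lgals3 (61.5%, 53.1%, 29.9% and 32.9%).

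Pooled over libraries, Gja1 in fibroblast-like nuclei exceeded what the free-RNA reference predicted. Over all libraries pooled, the 499 UMIs were 1.68 times the 297 expected (exact 95% interval 1.35 to 2.11), which argues against free muscle RNA as the whole source. All 4 libraries lay above the expected count, but the excess was larger in libraries 1 and 2, so the pooled ratio rests mostly on them. The expected counts all came from the same reference, with 96 Gja1 UMIs, so the libraries are not separate tests. No interval was computed by library, so the argument covers the pooled counts only. At the Gja1 to marker ratio of endothelial-like nuclei, endothelial RNA in fibroblast-like nuclei would bring 82.8 of the 202 excess UMIs. This is 41.1%, or 25.1% to 80.4% over the interval. Of the 629 Gja1 UMIs of endothelial-like nuclei, 205 were themselves expected from free RNA. That part is counted again here, so these values and those below overstate the endothelial part. Over the pooled counts, free and endothelial RNA together reach 1.28 times the free level, below the interval. That interval covers counting error only and not the spread between libraries, so no remainder is shown for each library. Endothelial RNA would bring 15.3 and 29.2 UMIs in libraries 3 and 4, where the excess was smaller. There it was not excluded as the whole source of the excess. How much of the excess endothelial RNA brings stays open, as do RNA of other classes and a free-RNA profile that differs from the reference. No biological explanation was tested, and that fibroblasts express Gja1 remains a hypothesis.

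Most muscle nuclei of libraries 1 and 2 fell in another cluster than those of libraries 3 and 4. With every muscle nucleus thinned to 1000 UMIs, the excess of own-library nearest neighbours over chance was at most 7.23 percentage points. It was at most 13.3 with all UMIs, too low for thinning to decide. Gene levels of these muscle nuclei were centred within each library before neighbours were sought, which takes out mean differences between libraries. The low excess could therefore come from that step. Clustered again after thinning, libraries differed by up to 57.5 points in the share of muscle nuclei in 1 cluster, against 66.9 points when the same nuclei were clustered again with all UMIs. Depth is therefore not shown to be the cause and not excluded as a part of it. The labels give no batch, region or heart per library, so no biological explanation was tested.

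Gjc1 was higher in border-zone-like muscle nuclei, while mural-like nuclei carried the highest Gjc1 of all classes measured. If mural RNA brought the difference, mural markers would have to rise with it, and their rise was 4.24%, 30.6%, 31.7% and 5.75% of that needed in libraries 1 to 4. The low values in libraries 1 and 4 argue against mural RNA as the whole source there, whereas in libraries 2 and 3 the rise lay between the bounds set before the test. A partial mural source could not be excluded, and no biological explanation was tested.

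Other splits of the 8 sums into 4 and 4 were fitted without the library term. Only the real split, 1 of 35, called as many genes in 4 comparisons, but the classes came from clustering the same counts, which fixes this outcome, so the splits do not decide on chance there. The real split called 10300 genes against cardiomyocyte-like, 6629 against macrophage-like, 5971 against endothelial-like and 1838 in activated fibroblast-like nuclei, with 0 for the highest other split in each. In the border-zone comparison, 2 of 35 splits called as many, 264 in the real one and 322 in the one setting libraries 1 and 4 against 2 and 3, so chance could not be excluded there. That split follows the libraries, and with the library term the real value was 1744. With the term, the 8 splits that part all pairs are too few for a share under 0.05. They gave 10626, 7264, 6870, 2630 and 1744 genes for the real split of the 5 comparisons and 0 for the highest other.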
